A study of Mus musculus with 12 samples.

How the data were processed

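The series holds RNA sequencing of pancreas from mice with caerulein pancreatitis, 6 libraries from C57BL/6J wild type mice and 6 from mice without functional Axl and Mertk, all at postnatal day 56. Per the labels' protocols, total RNA was taken up in Trizol, its integrity was checked on a Bioanalyzer, and libraries followed standard Illumina steps. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 and the genome build was mm10. The read counter, the gene annotation, the treatment of reads with several matches and the use of strand are not given in the sources used here. The deposited values are raw counts per gene, whole numbers in one table of 46095 genes and 12 columns, each column matched to its sample by the sample's title. Of these genes, 19888 had 0 counts in every library.

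Library totals ran from 10668637 to 15184371 counts. Data were simulated from the means, spread and library sizes of these 12 libraries, with 13681 genes tested for AMKO against wild type. In them 69.4% of 98 genes changed 2-fold and 99% of 96 genes changed 4-fold were recovered, and 9 of 172 calls were false. Genes were drawn independently of each other, without the correlation between genes that these libraries show, so the rates may not hold for the real data.

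Samples were grouped by the genotype in the labels. The labels do not say which mouse gave which sample, so if samples shared a mouse, p-values would measure only the spread between samples. Pairs of libraries within a genotype differed by far more than sampling noise (chi-square per degree of freedom of 9.93 to 73.33), so none was treated as a repeat deposit. AMKO was compared with wild type in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on raw counts, after TMM scaling and filterByExpr, with genotype as the only term and Benjamini-Hochberg adjustment over the 13743 genes tested. A gene was called changed at an adjusted p under 0.05, with no fold threshold. Log2 fold changes are AMKO minus wild type, with their standard errors (SE). Group levels are CPM, edgeR counts scaled to a common depth by TMM-scaled library sizes, as mean ± SD with n = 6 per genotype.

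There were 38 gene lists fixed from textbook knowledge before the data were examined, of which 36 had at least 3 tested members. Each was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, two-sided, and adjusted over the 36 lists. Camera with a correlation estimated for each list, and fry, were alternatives. Fry asks whether the members of a list differ between genotypes, not whether they differ more than other genes. A list score is the mean over its members of log2 CPM (prior count of 2) centred on the 12 libraries. The leukocyte score is the same mean over the neutrophil, macrophage, dendritic cell and B cell lists together, so it contains their genes. The acinar enzyme share is the percentage of a library's counts on the list of digestive enzymes, compared by a two-sided exact permutation test (SciPy 1.17.1). The relation of Cxcl2 to the neutrophil score was planned over all 12 libraries and within each genotype. Libraries turned out to fall into 2 separate clusters, so no correlation over all 12 is given. The correlation was computed within the cluster of 8, and within each genotype, which spans both clusters.

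Genes were placed on GRCm38, the assembly that mm10 names, by matching symbols to its annotation. Of the tested genes, 98.6% received a position. Calls within 10 Mb of Axl and of Mertk were compared with those elsewhere by two-sided Fisher exact tests. Near-identical copies were sought among transcript sequences with BLAST 2.17.0, at 95% identity or more over at least 300 bp. Genes that overlap another gene, or have such a copy, are named as uncertain, since the counting rule is not given in the sources used here.

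Genes named in the text follow a rule fixed at the same time as the lists. It takes Axl, Mertk and Tyro3. It takes the 10 largest changes and the 5 smallest p-values in each direction among called genes with a mean log2 CPM of at least 1, without predicted genes and pseudogenes. It takes up to 4 members per called list in its direction, and up to 4 called members, or otherwise the 2 most abundant, of uncalled lists. It takes up to 5 called genes near each locus. It also takes a fixed set of 22 chemokine, cytokine, leukocyte, acinar and stress genes whatever their result. From these, the text gives the genes that carry each group. Some genes that the rule takes are not reported here, and the search for libraries far from their group left them out. A gene outside the rule is named only with the statement that it was chosen after its values were seen.

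Other settings fixed before the data were examined were RLE, upper quartile and total-count scaling, scaling without the 50 most counted genes, no count filter and a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the acinar enzyme score as a covariate, other thresholds, windows of 5 and 20 Mb, and each library left out in turn. Settings added after seeing the data were a sex term, a term for WT 1 to 3, AMKO against WT 4 to 6 and against WT 1 to 3 alone, a leukocyte score covariate, AMKO 1 and WT 3 left out together, and the Cxcl2 relation and acinar share in the libraries with liver transcripts. Whether other groupings give as many calls was checked in 100 of the splits of the libraries into groups of 6, the real one included. Figures were drawn with matplotlib 3.10.9.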

Results

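RNA was sequenced from 12 pancreas samples of mice at postnatal day 56, 6 from C57BL/6J wild type mice (WT 1 to 6) and 6 from Axl-/-Mertk-/- mice (AMKO 1 to 6). AXL and MERTK are receptor tyrosine kinases that, with TYRO3, recognise dying cells through the bridging proteins GAS6 and protein S and restrain innate immune signalling. All mice had received 10 hourly intraperitoneal injections of caerulein at 100 µg/kg, a cholecystokinin analogue that overstimulates acinar cells and causes acute pancreatitis, and were killed 12 h after the first injection. The title of the series names CXCL2, neutrophils and necrosis, so the comparison asks how the inflamed pancreas differs between the genotypes. The strain background of the AMKO mice is not given in the sources used here. A difference of background across the genome therefore cannot be told apart from receptor loss. No untreated pancreas was analysed here, so the values compare genotypes within pancreatitis. Total counts per library ran from 10668637 to 15184371, and between 18548 and 20596 genes had at least 1 count.

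Both sexes were present in both genotypes. Counts of Xist and Ddx3y showed a female pattern in WT 2, 4 and 5 and AMKO 1, 3 and 6, and a male pattern in the other 6 libraries. Acinar digestive enzymes took 31.8% ± 2.95 of counts in wild type and 33.8% ± 3.64 in AMKO (SD, n = 6 each), a difference of 2.04 points that was within the spread between libraries (two-sided exact permutation p = 0.318). Mitochondrially encoded genes took 1.53% ± 0.29 and 1.45% ± 0.134 (exact permutation p = 0.545). One difference split the wild type group itself. WT 1 to 3 held 2 to 7 counts of albumin (Alb), the main plasma protein made by the liver, whereas WT 4 to 6 and all AMKO libraries held 141 to 309. Across those 9 libraries albumin averaged 16.2 CPM, against 0.397 CPM in WT 1 to 3, and 8 further genes, among them Apob and Apoa1, followed the same split. AMKO was therefore also compared with WT 4 to 6 alone, which share this trace, and with WT 1 to 3 alone.

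Axl, the targeted gene on chromosome 7 (25756500 to 25788924, GRCm38), was detected at 58.9 ± 12.3 CPM in wild type and 9.09 ± 2.21 CPM in AMKO, a log2 fold change of -2.69 (SE 0.18, adjusted p = 1.95e-06), with every AMKO library (66 to 187 counts) below every wild type library (545 to 1086 counts). Mertk on chromosome 2 (128698915 to 128803162) stood at 6.90 ± 2.96 CPM in wild type and 6.75 ± 2.39 CPM in AMKO (log2 fold change -0.03, SE 0.30, adjusted p = 0.968). Counts over a whole gene do not show which exons were read, so this value does not check whether the Mertk disruption was present. The third family member, Tyro3, did not pass the test (log2 fold change -0.14, SE 0.14, adjusted p = 0.576). Gas6 and Pros1, which encode the ligands, had log2 fold changes of -0.01 (SE 0.14) and -0.31 (SE 0.12), with adjusted p = 0.985 and 0.154. Gas6 overlaps Tmem255b and its counts are uncertain. In the list of ligands, TYRO3 and efferocytosis genes, 1 of 13 tested members passed the test. This was Itgav, an integrin subunit (-0.35, SE 0.09, adjusted p = 0.0424), lost in 9 of the 12 fits that left out 1 library, with adjusted p up to 0.0948, and against WT 4 to 6 or WT 1 to 3 alone (0.214 and 0.152). The list as a whole did not pass (adjusted p = 0.632).

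**Figure D1:**
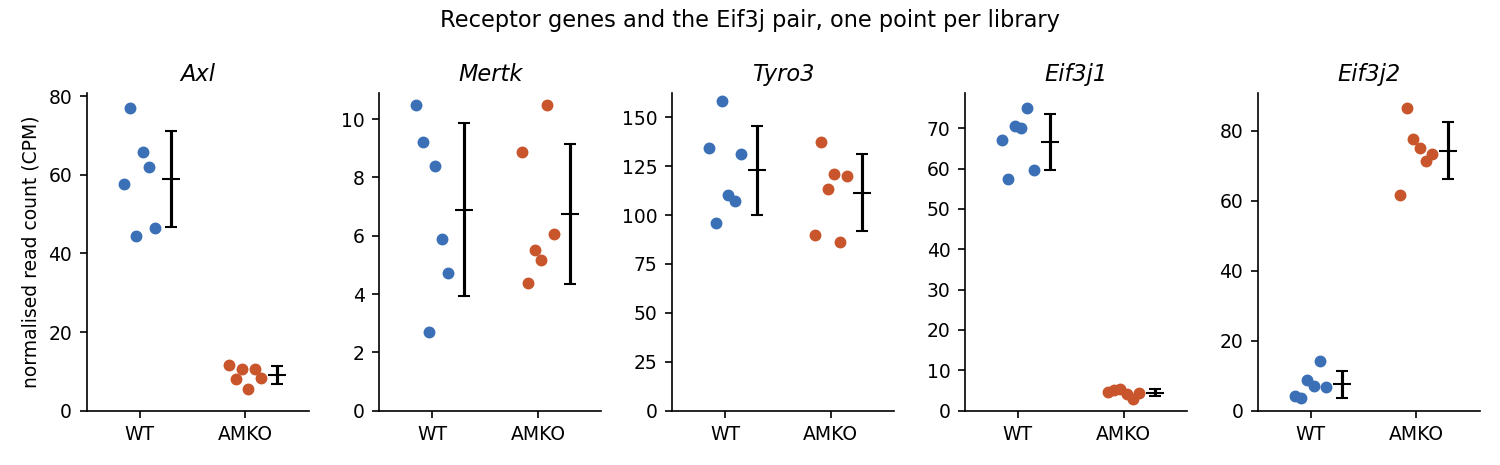
Normalised read counts (CPM, linear axis from 0) of Axl, Mertk, Tyro3, Eif3j1 and Eif3j2, with 1 point per library and mean ± SD in black. AMKO libraries lie below wild type for Axl and Eif3j1 and above it for Eif3j2, without overlap, while Mertk and Tyro3 overlap.

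Of 13743 genes tested, 794 differed between the genotypes, 331 higher and 463 lower in AMKO, and 139 of them by 2-fold or more (44 higher, 95 lower). The genes that rose most included Nos1ap, an adaptor of neuronal nitric oxide synthase, from 1.52 ± 0.56 to 20.7 ± 7.59 CPM (log2 fold change 3.75, SE 0.28, adjusted p = 7.89e-06). The acyl-CoA thioesterases Acot1 (1.55, SE 0.26, adjusted p = 0.00454) and Acot2 (1.49, SE 0.26, adjusted p = 0.00521) also rose, and since they share 95.8% of 826 aligned bases their counts are uncertain. Acot1 did not pass against WT 4 to 6 alone (0.0618), nor Acot2 against WT 1 to 3 alone (0.0782). Among genes that fell, Krt20, an intermediate filament keratin of gut and ductal epithelium, went from 782 ± 110 to 173 ± 55.9 CPM (-2.18, SE 0.19, adjusted p = 2.26e-05). Inhba, the activin A subunit, fell from 6.61 ± 2.09 to 1.46 ± 0.69 CPM (-2.15, SE 0.31, adjusted p = 0.00145). With WT 4 to 6 as the only wild type libraries, 167 genes were called (65 higher, 102 lower), and with WT 1 to 3, 231. Of the 794 genes, 164 and 192 were called again, and all 794 kept their sign in both. Both comparisons reuse libraries from which the 794 were called, so the kept signs are not independent support. The number of calls rested on single libraries, from 411 without AMKO 3 and 421 without AMKO 2 to 1121 without AMKO 1 and 1140 without AMKO 5. It fell to 524 without WT 2 and 505 without WT 4.

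Among the 36 gene lists tested, 13 differed, 7 higher and 6 lower in AMKO. None of the 13 held when the correlation between members was estimated from the data, and fry called 5. Of 100 groupings of the libraries into 6 and 6, the real one included, 37 gave at least 13 lists, so the number of lists is not more than other groupings of these libraries give. Taken singly, the duct list and the glycolysis and hypoxia list had a p as small in 2 of the 100 groupings, and the other 11 called lists in 5 to 35. Of the lists not called, 10 are described below, and the other 13 had adjusted p from 0.141 to 0.902. Among these 13 were the clock list (0.776) and the oxidative stress response, with 7 of 10 fitted values below 0 (median -0.22, adjusted p = 0.59).

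Whether neutrophil markers differed depends on how the libraries are compared. With genotype as the only term, none of 18 tested members passed the test, over all genes or adjusted over the list alone, and 14 had fitted values below 0 (median -0.17, list adjusted p = 0.409). S100a8 and S100a9, the calprotectin subunits, had log2 fold changes of -0.94 (SE 0.59, adjusted p = 0.375) and -0.99 (SE 0.53, adjusted p = 0.288), and Cxcr2, the neutrophil chemokine receptor, -0.48 (SE 0.59, adjusted p = 0.68). Without WT 6 the list was called lower (adjusted p = 0.0434, median -0.37), as it was without AMKO 1 and WT 3 together. Ly6g and Mpo had too few counts to be tested. The median was -0.03 against WT 4 to 6 alone and against WT 1 to 3 alone -0.53 (list adjusted p = 0.88 and 0.0925). With the replicate number as a block, a setting fixed before the data were examined, the list was called lower (median -0.32, adjusted p = 0.0204), as were S100a8 (-0.82, SE 0.17, adjusted p = 0.0229) and S100a9 (-0.94, SE 0.13, adjusted p = 0.00362). The labels do not say that equal numbers mark matched mice, so this result holds only if they do. With the leukocyte score as a covariate, S100a9 was called lower (adjusted p = 0.025) and the list was not (0.29). That score contains these genes, so the values only show their level relative to other leukocyte markers.

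Chemokines that attract neutrophils had lower fitted values in AMKO for all 5 tested members, and none passed the test over all genes. Cxcl2 stood at 9.06 ± 8.24 CPM in wild type and 5.27 ± 3.13 CPM in AMKO (log2 fold change -0.77, SE 0.58, adjusted p = 0.466), Cxcl1 at -0.80 (SE 0.42, adjusted p = 0.287) and Cxcl5 at -1.45 (SE 0.44, adjusted p = 0.0641). Adjusted over the list alone, 1 member was lower. The list had a median of -1.05 and did not pass (adjusted p = 0.073, and 0.673 with an estimated correlation). It was called lower without WT 3, WT 6 or AMKO 5, with adjusted p down to 0.00656, and against WT 4 to 6 alone (median -1.24, adjusted p = 0.0216), but not against WT 1 to 3 alone (adjusted p = 0.116). It was also called with the replicate number as a block (median -1.03, adjusted p = 0.00688) and with the leukocyte covariate (0.0289), where Cxcl5 passed too (0.0289 and 0.0259) and Cxcl2 did not (0.302 and 0.241), and without a count filter or without AMKO 1 and WT 3 together. Without WT 3 or WT 6, Cxcl5 was called lower as well, with adjusted p down to 0.0335.

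Libraries fell into 2 clusters of neutrophil score that did not follow genotype. WT 3, WT 6, AMKO 3 and AMKO 6 had scores of -1.41 to -1.27 and Cxcl2 at 0.86 to 1.34 log2 CPM, whereas the other 8 had scores of -0.07 to 1.73 and Cxcl2 at 2.08 to 4.57 log2 CPM. No correlation over all 12 libraries is given for that reason. The same 4 libraries were also the lowest for macrophage markers (-1.08 to -0.39, next -0.33) and dendritic cell markers (-1.23 to -0.27, next -0.17). Phagocyte NADPH oxidase genes were lowest in them too (-1.51 to -0.73, next -0.22), whereas B and plasma cell markers were lower in AMKO 4 (-1.93) than in WT 6 (-0.40). The clusters are therefore not particular to neutrophils, and Cxcl2 was not set against other leukocyte markers. Within the 8 libraries, Cxcl2 and the neutrophil score rose together (Pearson r = 0.883, exact permutation p = 0.0096, adjusted p = 0.038 over 4 tests; Spearman rho = 0.738, exact permutation p = 0.046, adjusted p = 0.092). Without WT 1 and AMKO 4, the libraries farthest from the median, r was 0.381. They held the highest and the lowest Cxcl2 of the 8 libraries (4.57 and 2.08 log2 CPM). Leaving them out narrows the range, which can lower r by itself, so this value cannot tell whether the relation rests on them. Among the 6 of these libraries with liver transcripts, r was 0.779 (exact permutation p = 0.075) and rho 0.714 (exact permutation p = 0.14). The cluster of 4 libraries is too small for a correlation. The planned correlations within each genotype span both clusters, which alone can give a high r. In wild type r was 0.964 (exact permutation p = 0.022) and rho 0.771 (exact permutation p = 0.1). In AMKO r was 0.977 (exact permutation p = 0.0056) and rho 0.943 (exact permutation p = 0.017).

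**Figure D2:**
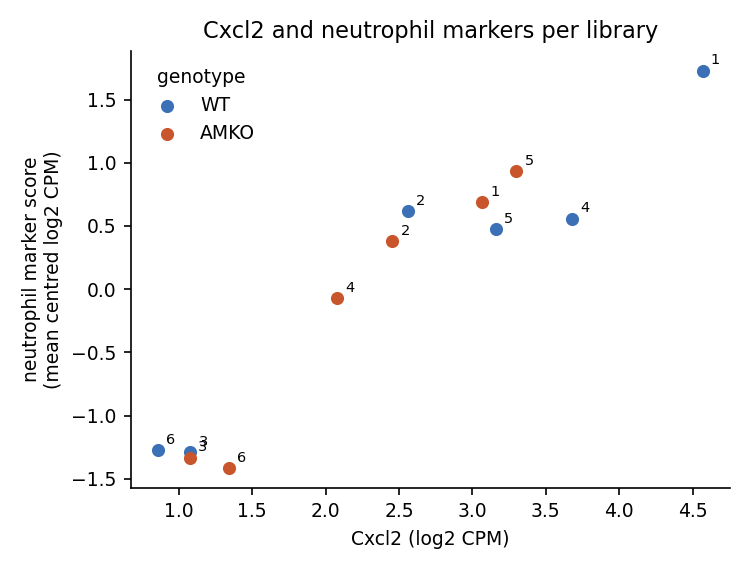
Neutrophil marker score (mean centred log2 CPM) against Cxcl2 (log2 CPM) with 1 point per library, coloured by genotype and numbered by replicate. WT 3, WT 6, AMKO 3 and AMKO 6 sit together at scores of -1.41 to -1.27, apart from the other 8 libraries.

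The monocyte chemoattractants Ccl7 and Ccl2 were lower in AMKO, and no list of monocyte chemoattractants was tested. Ccl7 fell from 47.6 ± 21.3 to 20.1 ± 5.84 CPM (-1.24, SE 0.27, adjusted p = 0.0169) and Ccl2 from 52.5 ± 27.5 to 21.6 ± 7.56 CPM (-1.27, SE 0.32, adjusted p = 0.0347), whereas Ccl24, an eosinophil chemoattractant, rose (1.05, SE 0.24, adjusted p = 0.0197). These were the 3 called members of 13 in the list of other chemokines. Adjusted over the list alone, 3 were higher and 3 lower. The list itself did not differ, and its median of 0.09 has the opposite sign to its test (adjusted p = 0.998). The Ccl2 call was lost in 7 of the 12 fits without 1 library (adjusted p up to 0.0837) and against WT 4 to 6 alone (0.0702), where Ccl7 kept it (0.0265) and Ccl24 did not (0.146). None of the 3 passed against WT 1 to 3 alone (0.123 to 0.169), where the log2 fold change of Ccl7 was -0.78, against -1.57 with WT 4 to 6. Il6 (-1.20, SE 0.50, adjusted p = 0.174) and Il1b (-0.92, SE 0.60, adjusted p = 0.396) did not pass, nor did any of 18 tested cytokine and NF-kB genes or their list (adjusted p = 0.443). Tnf was listed with 0 counts in every library, and the housekeeping gene Gapdh, chosen after its values were seen, with only 150 to 318, so a low value in this table need not mean low expression. Of 21 monocyte and macrophage markers, 1 passed the test. This was Mrc1, the mannose receptor, which rose from 49.5 ± 14.2 to 86.6 ± 17.8 CPM (0.81, SE 0.18, adjusted p = 0.0211, but 0.0524 without WT 4). Adgre1, which encodes F4/80, did not pass (0.24, SE 0.47, adjusted p = 0.805). The list had a median of 0.29 (adjusted p = 0.141) and was called higher without AMKO 3 or AMKO 6, with adjusted p down to 0.0126. It was also called higher with the leukocyte covariate (0.00972), the acinar covariate or 1 surrogate variable. The leukocyte score contains this list, so that call is only relative to other leukocyte markers. Mrc1 passed against WT 4 to 6 alone (0.0332) and not against WT 1 to 3 alone (0.178).

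Interferon-stimulated genes were lower in AMKO. All 29 tested members had fitted values below 0, with a median log2 fold change of -0.97. The AMKO libraries were not alike in this. Scores of AMKO 2, 3, 4 and 6 were -1.24 to -1.01, below every wild type library (-0.03 to 1.35), but AMKO 1 (0.47) and AMKO 5 (0.42) lay within the wild type range. These 2 libraries also had the highest scores for B and plasma cell markers (3.96 and 2.33) and for macrophage markers (0.90 and 1.03). Over all genes 10 passed the test, and 18 did when adjusted over the list alone. Rsad2, the antiviral enzyme viperin, fell from 193 ± 137 to 36.2 ± 10.4 CPM (-2.41, SE 0.40, adjusted p = 0.00401). Usp18, which limits interferon receptor signalling, fell from 31.6 ± 17.7 to 5.85 ± 3.44 CPM (-2.40, SE 0.41, adjusted p = 0.00446). Xaf1 (-1.88, SE 0.29, adjusted p = 0.00251) and Stat2, a transcription factor of the type I interferon response (-1.11, SE 0.15, adjusted p = 0.00127), fell too, and none of these 4 genes overlapped between the groups. The list passed with adjusted p = 6.04e-18 (0.472 with an estimated correlation; 0.0465 by fry). Its members move together across libraries, and in 7 of 100 groupings of the libraries, the real one included, its p was as small, while in 2 its median was as far from 0. Against WT 4 to 6 alone the median was -1.19 and against WT 1 to 3 alone -0.79, and all 4 named genes passed the test in both (adjusted p = 0.0164 to 0.0279 and 0.0102 to 0.04).

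**Figure D3:**
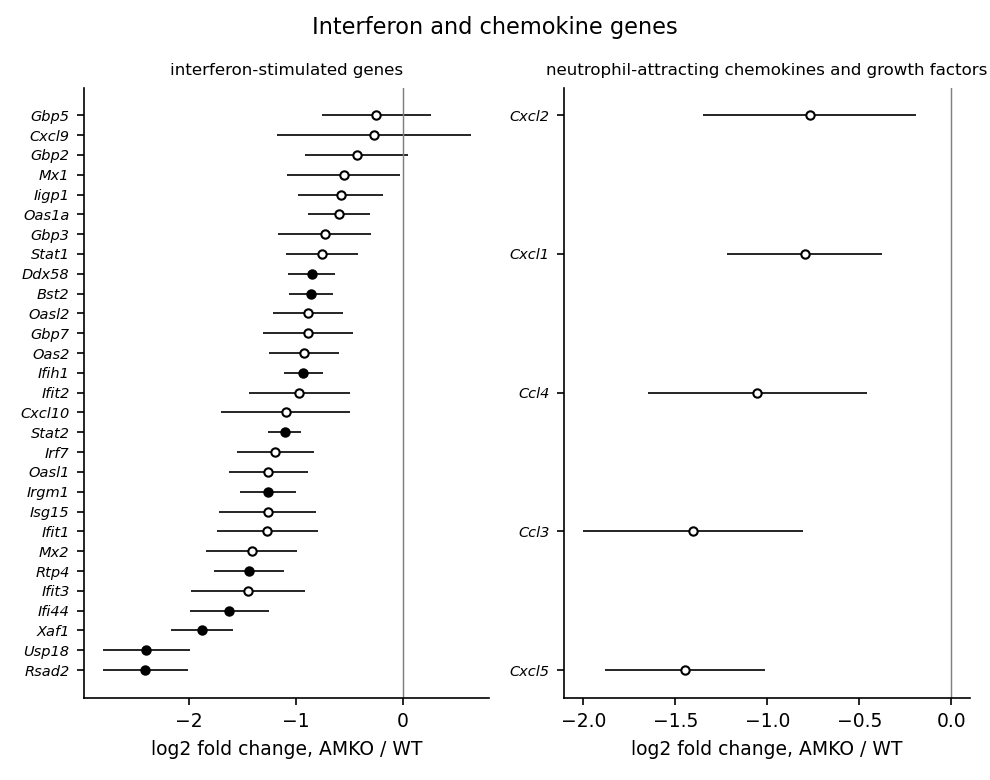
Log2 fold change (AMKO over wild type, ± SE) of the tested members of 2 lists. Filled points passed the gene test. All 29 interferon-stimulated genes lie below 0 and 10 are filled, and none of the 5 neutrophil-attracting chemokines is filled.

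Duct and acinar-to-ductal metaplasia markers were lower in AMKO as a group (median -0.28, adjusted p = 6.95e-06, and 0.253 with an estimated correlation). Of 16 tested members, 4 fell, and 5 did when adjusted over the list alone. Krt20 is given above. Epcam, an epithelial adhesion molecule, had a log2 fold change of -0.50 (SE 0.10, adjusted p = 0.00851), Spp1, which encodes osteopontin, -0.62 (SE 0.12, adjusted p = 0.0108) and Muc1 -0.53 (SE 0.12, adjusted p = 0.0195, but 0.0535 without AMKO 2). The ductal keratin Krt19 did not pass (1114 ± 102 and 1073 ± 195 CPM, log2 fold change -0.05, adjusted p = 0.831). Against WT 4 to 6 alone the list was still called (adjusted p = 6.14e-06), as was Krt20 (0.00169), while Epcam, Spp1 and Muc1 had adjusted p of 0.0594, 0.062 and 0.0697. The same held against WT 1 to 3 alone, with the list at 1.08e-04, Krt20 at 0.00197 and the other 3 at 0.119 to 0.189.

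Acinar genes did not move as a group. Of 23 tested digestive enzymes, 1 passed the test, also when adjusted over the list alone. This was the phospholipase Pla2g1b, which was lower (-0.65, SE 0.17, adjusted p = 0.0418), a call lost in 7 of the 12 fits without 1 library (adjusted p up to 0.0921) and against WT 4 to 6 or WT 1 to 3 alone (0.0974 and 0.216). Cpa1, carboxypeptidase A1, stood at 0.26 (SE 0.16, adjusted p = 0.36) and the amylase Amy2a5, which has near-identical copies, at -0.42 (SE 0.34, adjusted p = 0.5). Prss1 was listed with 0 counts throughout. The list had a median of 0.14 (adjusted p = 0.197) and was called higher without WT 3 or AMKO 1, with adjusted p down to 0.0118, without both, and with voom. Of 8 acinar identity factors, 2 rose. Ptf1a, a transcription factor that maintains acinar identity, went from 78.4 ± 19.4 to 181 ± 67.4 CPM (1.21, SE 0.26, adjusted p = 0.0145), and Bhlha15, which encodes MIST1, from 19.9 ± 3.64 to 36.2 ± 6.42 CPM (0.86, SE 0.14, adjusted p = 0.0032). Adjusted over the list alone, 3 were higher and 1 lower. The list did not pass (adjusted p = 0.141), but was called higher without AMKO 5 (0.0302), without AMKO 1 and WT 3 together and without a count filter. Bhlha15 passed against WT 4 to 6 alone (adjusted p = 0.0185) and Ptf1a did not (0.138), and neither passed against WT 1 to 3 alone (0.0583 and 0.0957).

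Regenerating and acute phase proteins were lower in AMKO as a group (median -0.39, adjusted p = 0.00955, and 0.483 with an estimated correlation). Of 19 tested members, 2 fell, and 4 did when adjusted over the list alone. Reg3g, a C-type lectin induced in injured acinar cells, started at 77.5 ± 32.4 CPM in wild type (log2 fold change -2.05, SE 0.46, adjusted p = 0.0192, but 0.0521 without AMKO 2), and Cp, ceruloplasmin, which overlaps Hps3, went from 326 ± 26.4 to 234 ± 22.6 CPM (-0.48, SE 0.08, adjusted p = 0.00454). Reg3b, also known as pancreatitis-associated protein, was at 2659 ± 1991 and 559 ± 530 CPM and did not pass (-2.25, SE 0.66, adjusted p = 0.0615). It was called lower without WT 2, WT 5 or AMKO 6, with adjusted p down to 0.0241. Against WT 4 to 6 alone neither Reg3g nor Cp passed (adjusted p = 0.0897 and 0.0812), and the list did (0.00085). With WT 1 to 3 alone Cp passed (0.0281), and Reg3g (0.109) and the list (0.162) did not. In the regulated cell death list, 2 of 17 tested members fell, also when adjusted over the list alone. Mlkl, the executioner of necroptosis, went from 21.7 ± 2.49 to 11.6 ± 2.48 CPM (-0.91, SE 0.15, adjusted p = 0.0032). The list did not pass (median -0.12, adjusted p = 0.162), but was called lower without AMKO 5 (0.033) and without AMKO 1 and WT 3 together. Mlkl passed against WT 4 to 6 alone (adjusted p = 0.0312) and not against WT 1 to 3 alone (0.0541).

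The unfolded protein response list was higher in AMKO through a few members. Of 23 tested, 5 rose and 1 fell, and 7 and 1 did when adjusted over the list alone. Chac1, which degrades glutathione, rose most (1.05, SE 0.19, adjusted p = 0.00682) and lies within 10 Mb of Mertk. Ppp1r15a, a phosphatase subunit that restores translation (0.96, SE 0.16, adjusted p = 0.00442), Herpud1 (0.75, SE 0.12, adjusted p = 0.0038) and the co-chaperone Dnajb9 (0.48, SE 0.10, adjusted p = 0.0145) followed. The fifth was Atf4, a transcription factor of this response named after its values were seen (0.57, SE 0.12). Sel1l, a degradation factor also named after its values were seen, fell (-0.49, SE 0.10). The chaperone Hspa5 stood at 0.00 (SE 0.18, adjusted p = 0.997) and Ddit3, which encodes CHOP, at -0.10 (SE 0.20, adjusted p = 0.807), and both overlap another gene. The list passed with a median of 0.02 (adjusted p = 0.00909, and 0.671 with an estimated correlation), but not against WT 4 to 6 alone (0.058, median -0.017). There, Chac1 and Ppp1r15a passed (adjusted p = 0.0279 and 0.0298) and Herpud1 and Dnajb9 did not (0.0635 and 0.17). With WT 1 to 3 alone other calls were made, with the list (0.00104), Herpud1 (0.0102) and Dnajb9 (0.0169) called and Chac1 (0.0657) and Ppp1r15a (0.0608) not. Each of these genes had a positive log2 fold change in both comparisons, so only the side of the threshold differed.

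Heat shock proteins were higher as a group (median 0.38, adjusted p = 0.00108, and 0.542 with an estimated correlation). Of 10 tested members 2 rose, and 5 did when adjusted over the list alone. The small heat shock protein Hspb8, which overlaps a predicted gene, had a log2 fold change of 0.86 (SE 0.15, adjusted p = 0.00526), and Hsp90aa1, which has near-identical copies, 0.54 (SE 0.13, adjusted p = 0.0264, lost without WT 4, WT 6 or AMKO 3 with adjusted p up to 0.0631). Glycolysis and hypoxia genes were higher too (median 0.16, adjusted p = 0.00429, and 0.185 with an estimated correlation), with 3 of 15 past the test and 6 adjusted over the list alone. Pgk1, phosphoglycerate kinase, which has near-identical copies, rose from 27.7 ± 2.82 to 41.0 ± 2.68 CPM (0.56, SE 0.08, adjusted p = 0.00145). Pfkfb3 (0.71, adjusted p = 0.0335) and Ndrg1 (0.57, adjusted p = 0.0364) were the other two, lost in 6 and 9 of the 12 fits without 1 library, with adjusted p up to 0.074 and 0.0888. Both lists were also called against WT 4 to 6 alone (adjusted p = 0.0216 and 0.00656), where Hspb8, Pgk1 and Pfkfb3 passed (0.0387, 0.0243 and 0.0423) and Hsp90aa1 and Ndrg1 did not (0.0989 and 0.134). They were called against WT 1 to 3 alone as well (1.75e-05 and 0.0039), where of the 5 genes only Pgk1 passed (0.0257; the others 0.0999 to 0.245).

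Immediate early genes passed as a list (median 0.18, adjusted p = 0.01, and 0.671 with an estimated correlation), with 3 of 14 higher and 4 adjusted over the list alone. Myc (0.76, SE 0.11, adjusted p = 0.00153) and Atf3 (0.81, SE 0.18, adjusted p = 0.0159) rose, as did Klf4 (0.49, adjusted p = 0.0428), which was lost in 9 of the 12 fits without 1 library (adjusted p up to 0.1). The list was lost without WT 3 (0.055) and against WT 4 to 6 alone (0.112), where Myc passed (0.019) and Atf3 and Klf4 did not (0.107 and 0.0949). It was called against WT 1 to 3 alone (7.63e-04), again with Myc (0.028) and without the other 2 (0.0979 and 0.264). Of 15 autophagy and lysosome genes, Sqstm1, the adaptor p62 (0.79, SE 0.18, adjusted p = 0.0219), and Gabarapl1 (0.52, SE 0.11, adjusted p = 0.0141) rose, and Ulk1, named after its values were seen, fell (-0.52, SE 0.14, adjusted p = 0.0376). Adjusted over the list alone, 3 were higher and 2 lower. The list passed (median 0.15, adjusted p = 0.0389, and 0.472 with an estimated correlation), but not without WT 2, WT 4, AMKO 2 or AMKO 5 (up to 0.0542) or against WT 4 to 6 or WT 1 to 3 alone (0.0683 and 0.0945), where Sqstm1 (0.0629 and 0.163) and Gabarapl1 (0.0519 and 0.152) did not pass either. Sqstm1 was lost in 5 of the 12 fits without 1 library, with adjusted p up to 0.0579. Ribosomal proteins passed with no called member among 17, over all genes or adjusted over the list alone (median 0.14, adjusted p = 0.01, and 0.671 with an estimated correlation), also against WT 1 to 3 alone (0.00327) but not against WT 4 to 6 alone (0.103).

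**Figure D4:**
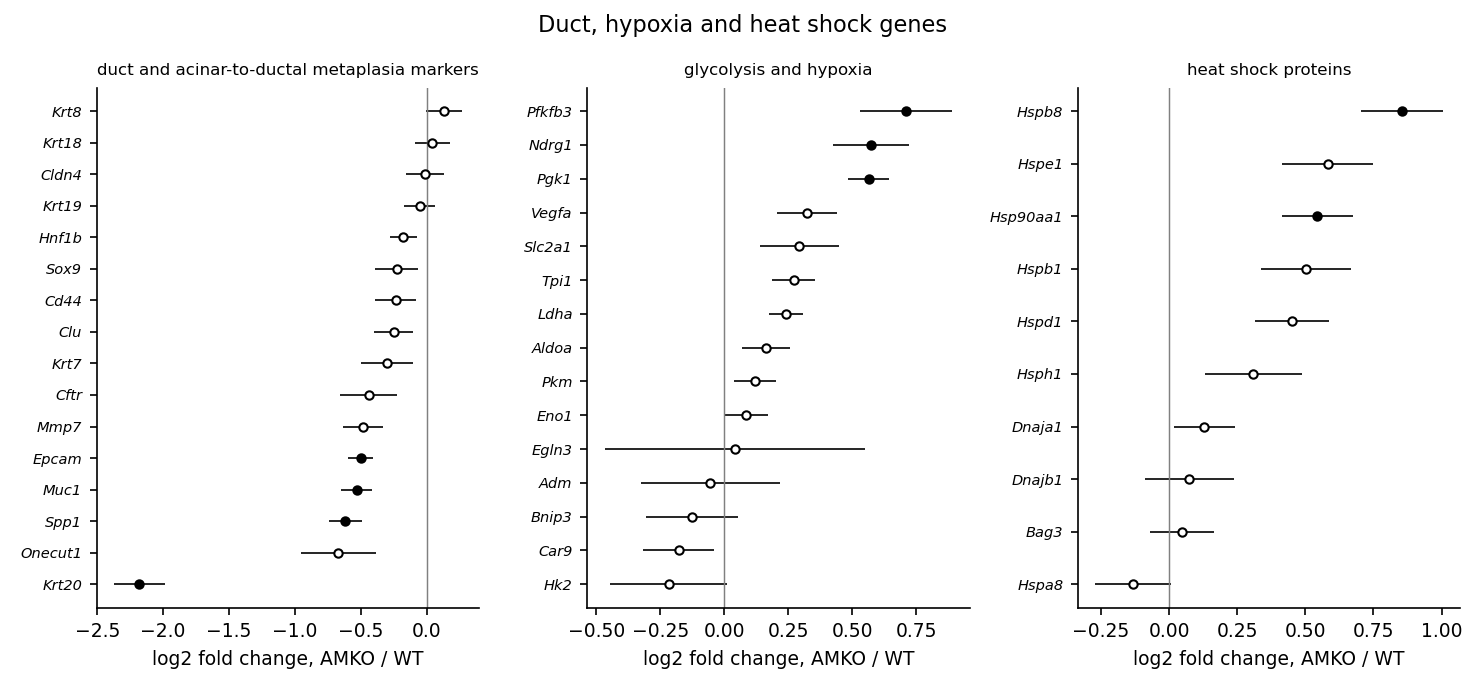
Log2 fold change (AMKO over wild type, ± SE) of the tested members of 3 lists, with filled points past the gene test. Krt20 at -2.18 lies apart from the other duct markers, and 3 glycolysis and hypoxia genes and 2 heat shock genes are filled above 0.

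Cholesterol synthesis genes were lower as a group (median -0.18, adjusted p = 0.01, and 0.483 with an estimated correlation). Of 17 tested members 2 fell, and 3 did when adjusted over the list alone. Insig1, a sterol sensor that holds back this pathway, fell from 583 ± 42.1 to 299 ± 62.9 CPM (-0.96, SE 0.12, adjusted p = 8.56e-04). Against WT 4 to 6 alone the list and Insig1 passed (adjusted p = 0.00085 and 0.019), and against WT 1 to 3 alone Insig1 did (0.0208) and the list did not (0.121).

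Fibroblast and stellate cell markers were lower as a group (median -0.39, adjusted p = 0.00909, and 0.671 with an estimated correlation), with a p as small in 34 of 100 groupings. AMKO 2, 3, 4 and 6 had scores of -0.71 to -0.22, but AMKO 1 (0.38) and AMKO 5 (0.32) lay above 4 of the 6 wild type libraries. Of 14 tested members, Pdgfrb (-0.62, SE 0.16, adjusted p = 0.033) and the matrix protein Postn (-0.97, SE 0.27, adjusted p = 0.046) fell, and 4 did when adjusted over the list alone. The calls were lost in 8 and 9 of the 12 fits without 1 library, with adjusted p up to 0.082 and 0.11, and both were lost with the replicate number as a block (0.0614 and 0.0769). The list passed against WT 4 to 6 alone (0.00085), as did Postn (0.031) but not Pdgfrb (0.18), and neither the list (0.0873) nor the 2 genes (0.243 and 0.153) passed against WT 1 to 3 alone. Of 11 endothelial markers, 1 passed, also when adjusted over the list alone. This was Kdr, the VEGF receptor, which fell from 41.3 ± 6.79 to 23.1 ± 5.43 CPM (-0.83, SE 0.15, adjusted p = 0.00752, with 0.0821 against WT 4 to 6 alone and 0.0463 against WT 1 to 3 alone). The list did not pass (adjusted p = 0.0757), but was called lower without WT 1, WT 5, AMKO 4 or AMKO 5 (down to 0.0257), with the sex term (0.0404) and without a count filter. Erythroid genes passed as lower (median -2.05, adjusted p = 0.035, and 0.671 with an estimated correlation), with 0 of 4 members past edgeR's test over all genes and 4 adjusted over the list alone. WT 3 held most globin counts, and without it the median was -0.78 and the list was not called (0.055). It was also lost without AMKO 1, AMKO 2 or AMKO 4 (up to 0.0591) and against WT 4 to 6 alone (0.0596), but not against WT 1 to 3 alone (0.00327). Hepatocyte markers passed as higher (median 0.82, adjusted p = 0.0138, and 0.671 with an estimated correlation) with 0 of 7 members past the test, over all genes or adjusted over the list alone. They follow the split of the wild type libraries, since against WT 4 to 6 alone the median was 0.03 (adjusted p = 0.88) and against WT 1 to 3 alone 3.46 (6.34e-31).

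Genes around Mertk were called far more often than others. Within 10 Mb of its start, 40 of 184 tested genes (21.7%) differed, 14 higher and 26 lower, against 5.61% of genes away from both loci, an odds ratio of 4.67 (95% interval 3.18 to 6.73, Fisher exact p = 2.69e-13). The 5 with the smallest p were Eif3j1, Adal, Lcmt2, Rhov and Fermt1. Eif3j1, a translation initiation factor subunit on chromosome 2 (122028580 to 122053632), fell from 66.6 ± 6.87 to 4.43 ± 0.90 CPM (-3.91, SE 0.14, adjusted p = 7.52e-10), while its near-identical copy Eif3j2 on chromosome 18 (43475418 to 43477836; 99.4% identity over 2379 bp) rose from 7.48 ± 3.87 to 74.3 ± 8.10 CPM (3.33, SE 0.26, adjusted p = 9.18e-06), so the counts of either are uncertain. Adal (2.24, SE 0.15, adjusted p = 1.95e-06) and Lcmt2 (3.04-fold, adjusted p = 1.94e-05) overlap each other. Rhov, a small GTPase, rose (1.47, SE 0.15, adjusted p = 1.55e-04), and Fermt1, an integrin activator of epithelia, fell (-2.13, SE 0.23, adjusted p = 2.25e-04). Just outside the window, the proapoptotic gene Bmf fell from 38.0 ± 11.4 to 4.46 ± 1.55 CPM (-3.07, SE 0.25, adjusted p = 1.11e-05). All of these also passed against WT 4 to 6 alone (adjusted p = 0.0104 or less) and against WT 1 to 3 alone (0.0119 or less). Around Axl, 8 of 274 tested genes (2.92%) were called, among them Ech1 (0.85, SE 0.10, adjusted p = 2.74e-04), with an odds ratio of 0.51 (95% interval 0.22 to 1.02, Fisher exact p = 0.0605).

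**Figure D5:**
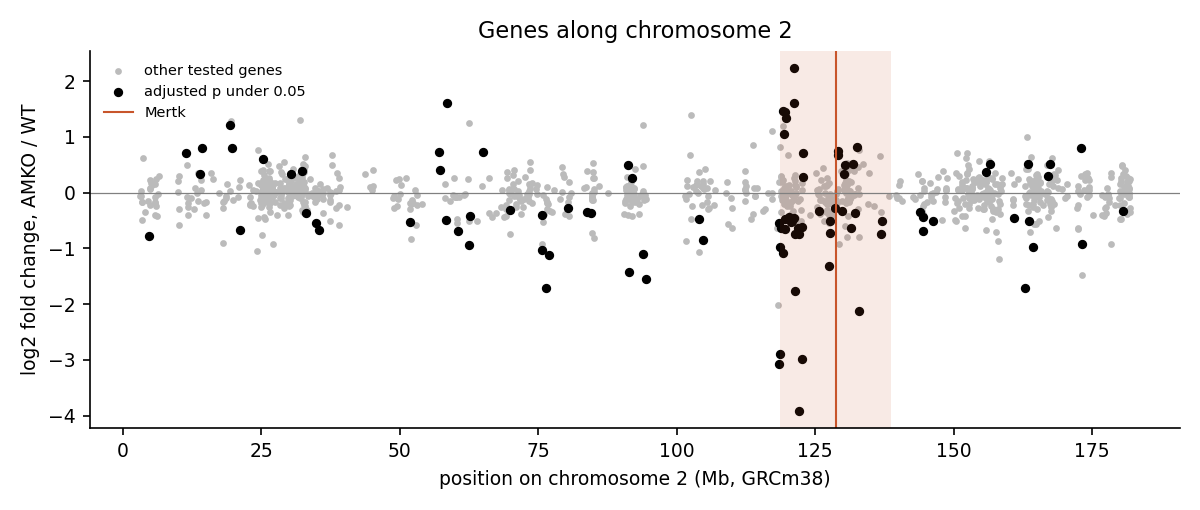
Log2 fold change (AMKO over wild type) of tested genes along chromosome 2 (Mb, GRCm38), with genes past the gene test in black. The band marks 10 Mb to either side of Mertk, in which 40 of 184 genes are called.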

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

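In 11 of 214 groups of 6 libraries, 1 library lay far from the other 5 for a gene, list score or share, by a gap to its neighbour above Dixon's 95% value for 6 samples. Chance alone gives about 1 in 20 groups, or 10.7 here, so the number as a whole is near what chance gives. No explanation was tested for any of them.

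Erythroid genes stood out in both genotypes. WT 3 had a score of 3.44 with the next wild type library at 0.65 (gap over range 0.772), and AMKO 5 a score of 1.03 with the next at -0.54 (0.637). Among tissue genes, Amy2a5 was lowest in WT 3 (7.98 against 8.97 log2 CPM; 0.646), Mlkl lowest in AMKO 6 (2.80 against 3.57; 0.745) and Ndrg1 lowest in AMKO 5 (8.66 against 9.37; 0.777). Phlda2, an imprinted growth regulator whose log2 fold change was 1.71 (SE 0.33, adjusted p = 0.009, but 0.0678 against WT 4 to 6 alone and 0.088 against WT 1 to 3 alone), was lowest in WT 6 (-1.04 against -0.07; 0.689). The DNA replication gene Mcm6 was highest in WT 6 (6.49 against 6.27; 0.759), and Cxcl5 lowest in AMKO 6 (-1.07 against 0.51; 0.758).

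Near Mertk, Eif3j1 was lowest in AMKO 5 (1.56 against 2.14 log2 CPM; 0.657), and Adal was highest in WT 3 (2.81 against 2.18; 0.775) and in AMKO 6 (4.70 against 4.43; 0.642). These gaps are small beside the differences between genotypes in both genes, which did not overlap.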

How the results depend on the processing

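All 794 called genes kept their sign in each alternative that gave them a value. Each alternative used the same libraries or a part of them, so this is not independent support. Calls shared with the reported set were 749 with RLE factors, 428 with total-count scaling, 794 with DESeq2, 780 with voom and 269 with a term for WT 1 to 3. That term, the comparisons with WT 1 to 3 or WT 4 to 6, the sex term, the leukocyte covariate, the fit without AMKO 1 and WT 3 and the Cxcl2 relation among libraries with liver transcripts were chosen after seeing the data. Camera was not run on DESeq2. No scaling moved the share of calls that were higher by more than 10 points, nor the median of all genes by more than 0.04 on the log2 scale. The acinar enzyme share differed by 0.95 to 3.21 points without 1 library, and never passed its exact test. Fewer samples, a stricter threshold or fewer degrees of freedom lower a count by construction, and for the other changes the cause was not tested. Ly6g and Mpo had too few counts to be tested.

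The count of genes changed, the count of genes higher in AMKO and the count of genes lower in AMKO were 456, 163 and 293 with total-count scaling, 1267, 625 and 642 with DESeq2, 1664, 809 and 855 with voom, 1489, 678 and 811 with 1 surrogate variable, 1494, 676 and 818 with the leukocyte covariate, 283, 107 and 176 with the term for WT 1 to 3, 167, 65 and 102 against WT 4 to 6, and 231, 76 and 155 against WT 1 to 3. At an adjusted p under 0.01 they were 225, 74 and 151, under 0.10 they were 1465, 656 and 809, and at 2-fold or more 139, 44 and 95. Without AMKO 1 and WT 3 together, 533 genes were higher. Leaving out 1 library gave 411 to 1140 changed, 149 to 625 higher and 262 to 550 lower. Lists called numbered 8 with the term for WT 1 to 3, 0 with an estimated correlation and 5 with fry. The correlation of Cxcl2 with the neutrophil score was 0.381 without the 2 farthest libraries and 0.779 in those with liver transcripts.

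Both genotypes use the same replicate numbers, and the labels do not say whether they mark matched mice. Same-numbered libraries correlated at -0.16 to 0.346, above 0 in 4 of 6 pairs, and numbers 3 and 6 had low neutrophil scores in both genotypes. Only for numbers 1 and 6 was the same-numbered AMKO library the best partner of its wild type library, and all 6 pairs were of opposite sex. Pairing stays open. With the replicate number as a block, 910 genes were called, 679 of them among the 794. In the same fit Mertk stood at 0.012, Gas6 at 0.008, Hspa5 at 0.015 and the other chemokines median log2 fold change at -0.037.

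Values close to 0 changed sign. Mertk was at 0.059 with 1 surrogate variable, 0.075 with the acinar covariate, 0.099 with the term for WT 1 to 3, 0.11 against WT 4 to 6, 0.033 with the leukocyte covariate, and -0.19 to 0.14 without 1 library. Gas6 was at 0.005 with RLE, 0.0 without the 50 most counted genes and without a count filter, 0.006 with DESeq2, 0.14 against WT 1 to 3 and -0.10 to 0.059 without 1 library. Hspa5 was at 0.007 with RLE, 0.006 without a filter, 0.009 with DESeq2, 0.099 with voom, 0.066 with the term for WT 1 to 3, 0.079 against WT 4 to 6, 0.002 with the leukocyte covariate, 0.22 without AMKO 1 and WT 3, and -0.13 to 0.16 without 1 library. Krt19 was at 0.057 against WT 1 to 3, 0.026 without AMKO 1 and WT 3, and -0.13 to 0.029 without 1 library. Without AMKO 1 and WT 3, Tyro3 was at 0.015 and Ddit3 at 0.042. Adgre1 was at -0.26 with voom and -0.33 to 0.52 without 1 library.

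Lists changed the sign of their median or the direction of their test too. The median of other chemokines was 0.078 with upper quartile factors, 0.046 with total-count scaling, 0.17 without the 50 most counted genes, 0.002 with 1 surrogate variable, 0.011 with the acinar covariate, -0.035 with the leukocyte covariate and -0.19 to 0.29 without 1 library. Acinar enzymes were at -0.15 when the 50 most counted genes, many of them enzymes, were left out. Neutrophil markers were at -0.044 with the term for WT 1 to 3 and -0.55 to 0.15 without 1 library, and macrophage markers at 0.022 without AMKO 1 and WT 3. The called hepatocyte list was at 0.014 with the term for WT 1 to 3 and 0.029 against WT 4 to 6. The called unfolded protein response list was at -0.031 with that term, -0.017 against WT 4 to 6 and -0.014 to 0.088 without 1 library.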

Other observations

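Clock genes held the members with clear differences but not a shared direction. Of 14 tested, Dbp, a clock output gene that overlaps Sphk2, fell from 15.4 ± 8.01 to 4.59 ± 0.97 CPM (log2 fold change -1.75, SE 0.31, adjusted p = 0.00569), and the repressor Cry1 rose (0.44, SE 0.10, adjusted p = 0.0192, but 0.0517 without AMKO 2). Adjusted over the list alone, 4 were higher and 4 lower, and the list did not pass (adjusted p = 0.776). Both genes kept their calls against WT 4 to 6 alone (adjusted p = 0.0332 and 0.047), and only Dbp did against WT 1 to 3 alone (0.00619 and 0.189). The labels give no time of day at which mice were killed. A term for sex called 7 genes, and edgeR called 0 genes for a genotype difference that depended on sex, with 457 of 14522 tested genes (3.15%) at an unadjusted p under 0.05; no other tool was run for it.

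Whether other groupings of the libraries give as many calls was checked with 100 groupings into 6 and 6, the real one included. No other grouping gave as many changed genes (794, highest other 33), higher genes (331, highest other 28) or lower genes (463, highest other 28). Thus 1 of 100 reached each count, the smallest share that 100 groupings can give. Chance is argued against for these counts, but this check cannot exclude it. All other groupings mixed the genotypes, which adds a difference between genotypes to the spread within groups. For the number of lists, chance is not argued against, since 37 of 100 groupings gave 13 or more (highest other 24). The tests below of the Eif3j1 and Pcna sums, of near-identical pairs, of the rest of chromosome 2, of the interferon list within 9 libraries, of the macrophage markers and of albumin were chosen after the results were seen.

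Calls gather around Mertk, and Eif3j1 fell while its near-identical copy Eif3j2 rose by about as many counts. An effect of the disrupted locus on its immediate neighbours is argued against as the whole cause, because genes 2 to 20 Mb away were also called more often (odds ratio 3.951), on both flanks (4.88 and 2.66). Reads moving between copies may account for the Eif3j pair, since their summed counts differed by only 0.088 on the log2 scale (SE 0.097). Whether reads moved between copies among the other calls as a whole cannot be told. Apart from the Eif3j loci, 2 pairs of near-identical genes were called in opposite directions, against a median of 1 and a highest of 4 in 100 random draws. These pairs included Pcna (-0.368) and Pcna-ps2 (5.598), a pseudogene named after its values were seen. Their summed counts differed by -0.185 on the log2 scale (SE 0.099, adjusted p = 0.292 in edgeR), so moving reads may account for this pair too. A chromosome segment of another strain carried along with the disrupted Mertk is a candidate explanation for the cluster, since the rest of chromosome 2 had no excess of calls (odds ratio 1.069, Fisher exact p = 0.639). Gene counts hold no alleles, so the segment itself was not seen, and an effect of receptor loss on these genes stays open.

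Interferon-stimulated genes were lower in AMKO, and chance cannot be excluded for the list, since 7 of 100 groupings gave it a camera p as small (1.68e-19, smallest other 4.14e-24), although only 2 gave a median as far from 0 (-0.969, highest other 1.085). The split of the wild type libraries is argued against, because the median within the 9 libraries with liver transcripts was -1.188. With the leukocyte score as a covariate the median of the interferon list was -1.123. Leukocyte content as that pooled score measures it is therefore argued against as the whole cause. The score cannot decide for each kind of leukocyte, since it includes B and plasma cell markers, which were highest in AMKO 1 and AMKO 5 (3.96 and 2.33). The macrophage markers, at a median of 0.292, cannot decide whether fewer leukocytes are the cause either, since AMKO 1 and AMKO 5 had the highest scores (0.90 and 1.03). AMKO 2, 3, 4 and 6, with low interferon scores, had macrophage scores of -0.66 to 0.00. Wild type macrophage scores ran from -1.08 to 0.35. A part played by leukocyte content stays open. An effect of receptor loss may underlie the difference, as a hypothesis that these 12 libraries leave open. A difference of strain background could underlie it too, and cannot be told apart from receptor loss here.

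Liver transcripts were near 0 in WT 1 to 3 and present in the other 9 libraries. Genotype is argued against, since albumin in WT 4 to 6 was 39.5 times its level in WT 1 to 3 and 0.95 times that in AMKO. Pieces of liver taken with the pancreas are argued against by the evenness of albumin over the 9 libraries, with a coefficient of variation of 14.2%. A difference between library batches stays open and was not tested, as the labels give no batch, and so no comparison of AMKO with WT 1 to 3 can separate it from genotype.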
